A study of Mus musculus with 6 samples.

How the data were processed

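Whole uteri of mice on gestational day 4 were profiled by RNA sequencing in 6 libraries, 3 labelled Mettl3 f/f and 3 labelled Mettl3 d/d. Mettl3 encodes the catalytic subunit of the enzyme complex that writes N6-methyladenosine on RNA. By the usual notation f/f stands for a floxed allele and d/d for its deleted form, but the labels state neither the Cre driver nor the deleted exons. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these libraries.

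The authors deposited 1 table per library with 1 expression value for each of 21936 genes. The values were taken as FPKM, fragments scaled by gene length and by the mapped fragments of the library, as the authors deposited them. The unit was inferred, because the file headers give none. The values are decimals, their totals of 535043 to 625575 differ between libraries, and Cufflinks writes FPKM. Estimated counts, which can be decimals, and TPM cut to a part of the genes are not excluded by this. Per the submitters' processing notes, HISAT2 2.2.1 and Cufflinks 2.2.1 were used, and the builds mm9 and mm10 are both listed. The role of each build, the gene annotation, the options and any use of strand are not given in the sources used here. Cufflinks assigns fragments that fit several places, so the values of close paralogs and of genes with many pseudogenes depend on that step. Gapdh was listed at 2.63 to 9.48 FPKM and Ppia at 3.00 to 9.25, against 4802 to 9447 for Actb and 3641 to 4278 for Eef1a1, so genes with many near-identical copies are uncertain here.

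A value of 0 may be a failed estimate. Kif11, a mitotic motor gene, was listed at 0 in all 6 libraries although other mitotic genes were not, and Egr2 and Fzd6 were as well. In all, 4180 genes (19.1%) were listed at 0 in all 6 libraries. Genes with a 0 in any library are therefore given by library, without a mean, an SD or a fold, except that the log2 fold change of S100a9 is given beside its values where it turned direction.

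The files give no read numbers, so the absolute depth is unknown. Among genes below 0.3 FPKM, the most frequent ratio between libraries was taken as the ratio of their 1-fragment steps, which estimates the relative depth. Against f/f replicate 1 it was 1.01 in f/f replicate 2, 1.01 in f/f replicate 3, 0.998 in d/d replicate 1, 0.976 in d/d replicate 2 and 0.935 in d/d replicate 3. Only ratios near equality were searched, so a large difference in depth would not have been found. No counting interval can be given without the depth.

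Where several rows shared a symbol, the row with the highest mean was kept, which removed 36 rows. Genes were kept at an FPKM of at least 1 in at least 3 of the 6 libraries, which left 12979. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model of genotype, empirical Bayes with an intensity trend, two-sided) and Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05. Log2 fold changes are labelled d/d minus f/f on the log2(FPKM + 1) scale, which understates the change of genes with low values. Folds are ratios of mean FPKM.

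In all, 31 gene lists were written before the data were examined: 3 main lists, 14 supporting lists and 14 lists of cell type markers. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera compares the members of a list with all other genes. Its estimated-correlation form and fry, which tests whether the genes of a list move one way on balance, were the alternatives. The lists rest on general knowledge of the uterus and share members. Hand2 and Hoxa10 stand in the progesterone and decidual lists, Ihh, Ptch1 and Gli1 in the progesterone and hedgehog lists, and collagen genes in the matrix and stroma lists.

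The genes named were chosen by a rule set before the data were examined. Mettl3, Pgr and Esr1 were always named. To these came the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 FPKM in 1 genotype and no overlap between the genotypes, leaving out clone and locus names. Members of the 3 main lists could be named, and up to 4 members of every other list in order of unadjusted p. Genes named outside this rule are said to be. Some genes that fall under the rule are not reported here.

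The test was run on simulated data with the real genes and library numbers, with 200 of 12979 genes changed, as means of 10 draws. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2, so recovery of genes with lower values was not measured. The shares of false calls hold for 200 changed genes. How well the test did depended on the spread simulated. With each genotype's own spread as measured, 42.9%, 81.4% and 92.9% of the genes changed by 1, 2 and 3 on the log2 scale were recovered, and 21.8%, 16.7% and 18.1% of the calls were false. With each genotype's spread shrunk over genes, recovery was 37.4%, 93.1% and 98.8% and 11.6%, 10.1% and 10.4% of the calls were false. With 1 spread for both genotypes, recovery was 33.4%, 94.7% and 98.1% and 7.23%, 5.73% and 6.35% of the calls were false. The shrunk and common spreads, and the averaging over draws, were added after a first draw with the measured spreads had been seen. The nominal share of false calls is 5%. It was exceeded with 1 spread for both genotypes too, and most with each genotype's own spread as measured. The adjusted p-values here may therefore be too small, most of all where the genotypes differ in spread.

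Gene coordinates are from GENCODE on GRCm38 (mm10), given as 1-based positions. Of the gene identifiers in the files, 21817 were found there and 119 were not. Since the authors' build is not settled, the coordinates describe the annotation and not the authors' own gene models. Alternatives were other pseudocounts (0.1 and 0.5), no filter, a filter at a mean of at least 5 FPKM, quantile, upper quartile and median-of-ratios scaling, no trend, weights per library, a block for the replicate number, each library left out in turn and the other list tests. Weights per genotype, and counts of changed list members with each library left out, were added after the data had been examined. Figures were drawn with matplotlib 3.10.9.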

Results

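RNA was measured in whole uteri on gestational day 4, counted from the vaginal plug as day 1, which is around the time at which the mouse uterus becomes ready for implantation. The 6 libraries fell into 2 genotypes by their labels, 3 Mettl3 f/f and 3 Mettl3 d/d, and the comparison asks which genes differ in the uterus between the 2 labelled genotypes. Each library had a value above 0 for 15978 to 16359 genes and summed to 535043 to 625575 FPKM. Genes of the mitochondrial genome made up 6.21% to 8.21% of the FPKM. The absolute depth is unknown, and the relative depths were estimated at 0.935 to 1.01 times that of f/f replicate 1. The f/f libraries were close to one another (Spearman correlation over genes 0.984 to 0.988). The libraries labelled d/d differed among themselves (0.951 to 0.965) about as much as they differed from the f/f libraries (0.945 to 0.968). Of these, d/d replicate 1 correlated slightly more with f/f replicates 1, 2 and 3 (0.968, 0.967 and 0.968) than with d/d replicates 2 and 3 (0.962 and 0.965). The latter 2 correlated at 0.945 to 0.951 with the f/f libraries and at 0.951 with each other. The median SD of a gene on the log2 scale was 0.126 among the f/f and 0.301 among the labelled d/d libraries.

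Mettl3 itself (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, minus strand, protein coding, GRCm38) was not lower in the libraries labelled d/d. It stood at 30.3, 29.8 and 26.3 FPKM in f/f replicates 1, 2 and 3 and at 42.9, 30.1 and 46.5 in d/d replicates 1, 2 and 3. The log2 fold change was 0.43 (SE 0.19, 95% interval -0.02 to 0.88, limma adjusted p = 0.202). An exact two-sided permutation test gave p = 0.2, and 0.1 is the smallest p that 3 against 3 libraries allow. Without d/d replicate 2 the log2 fold change was 0.62 (adjusted p = 0.0422). A value over the whole gene also counts exons outside a deleted part, and the part deleted is not given in the sources used here, so it does not check the genotype labels. Mettl3 also overlaps Tox4 on the other strand by 1561 bp. All directions below therefore rest on the labels, and "labelled d/d" is meant wherever d/d is written.

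No change passed in the steroid receptor genes through which the ovarian hormones act on the uterus, and the intervals leave room for changes. Pgr, the progesterone receptor gene (chromosome 9, 8899833 to 8968611), averaged 23.5 ± 0.428 FPKM in f/f and 33.2 ± 16.0 in labelled d/d libraries (SD, n = 3 each), a log2 fold change of 0.36 (95% interval -0.49 to 1.22, limma adjusted p = 0.553, exact permutation p = 0.4). Esr1, the estrogen receptor alpha gene (chromosome 10, 4611593 to 5005614), averaged 47.5 ± 4.74 and 48.0 ± 9.07 FPKM, a log2 fold change of 0.00 (95% interval -0.42 to 0.42, exact permutation p = 0.9). Among the 14 measured steroid receptors and coregulators none passed over all genes, while 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.721), and 2 were lower over all genes without d/d replicate 1. The members with the lowest p were Ncoa3, a coactivator gene, at 11.3 ± 1.82 against 17.7 ± 0.677 FPKM, and Pgrmc2 at 43.1 ± 3.57 against 26.4 ± 5.44 (limma adjusted p = 0.0614 and 0.0639).

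Of 12979 genes tested, 947 changed in the labelled d/d uteri (limma adjusted p under 0.05), 453 higher and 494 lower. Of these, 623 changed at least 2-fold, 295 higher and 328 lower. The largest rise on the log2(FPKM + 1) scale was that of Lcn2, which encodes the iron-carrier-binding protein lipocalin 2 (chromosome 2, 32384633 to 32388252). It averaged 9.29 ± 5.70 FPKM in f/f and 1632 ± 1288 in labelled d/d libraries (n = 3 each), a log2 fold change of 6.78 (SE 1.00, adjusted p = 0.0220). Spink12, a protease inhibitor gene, rose by 6.08, Gabrp by 5.13, the gap junction gene Gjb2 by 4.97, the complement gene C3 by 4.83, Clca1 by 4.65, the surfactant protein gene Sftpd by 4.56 and Sprr2f by 4.49 on the log2 scale. By the ratio of mean FPKM, Spink12 rose more than Lcn2 (278-fold against 176-fold). The mucin genes Muc4 and Muc20 rose by 5.03 and 4.74. They overlap on opposite strands by 4973 bp, so without stated use of strand their fragments cannot be told apart in that part. Sprr2f and Clca1 have close paralogs and their values are uncertain.

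Among the largest falls were Angptl7 (log2 fold change -5.02), Maob, which encodes a monoamine oxidase (-4.84), Npl (-4.41), the glucose transporter gene Slc2a3 (-4.23), Rims3 (-4.01), the membrane peptidase gene Mme (-3.98), Acbd7 (-3.94) and Wfdc3 (-3.88). Maob fell from 110 ± 13.6 to 2.93 ± 1.14 FPKM (n = 3 each), 37.4-fold by the means (adjusted p = 0.00365). Angptl7 overlaps Mtor on the other strand by 5278 bp. Spink1 was at 31.0, 36.9 and 20.7 FPKM in f/f replicates 1 to 3 and at 0.455 in d/d replicate 1, and was listed at 0 in d/d replicates 2 and 3 (adjusted p = 0.00365). Pla2g10, a secreted phospholipase gene, was at 55.8, 57.4 and 65.3 FPKM in f/f libraries and 11.3 in d/d replicate 1, and was listed at 0 in d/d replicates 2 and 3 (adjusted p = 0.0411). The counts fell with any f/f library left out: 0 genes were called without f/f replicate 1 (2292 at an unadjusted p under 0.05, against 3460 with all libraries), 30 without f/f replicate 2 and 111 without f/f replicate 3, and the counts of at least 2-fold changes were the same 0, 30 and 111. With d/d replicate 1, 2 or 3 left out, the count of changed genes rose instead, to 1319, 1367 and 1005. The fit takes 1 spread per gene over both genotypes, and the labelled d/d libraries had the larger spread. In 4665 genes (35.9%) the values of the genotypes did not overlap. Chance gives 10% where all 6 libraries have the same spread. With the larger spread of the labelled d/d libraries it can give more, so 10% is not a fair yardstick for this share.

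**Figure D1:**
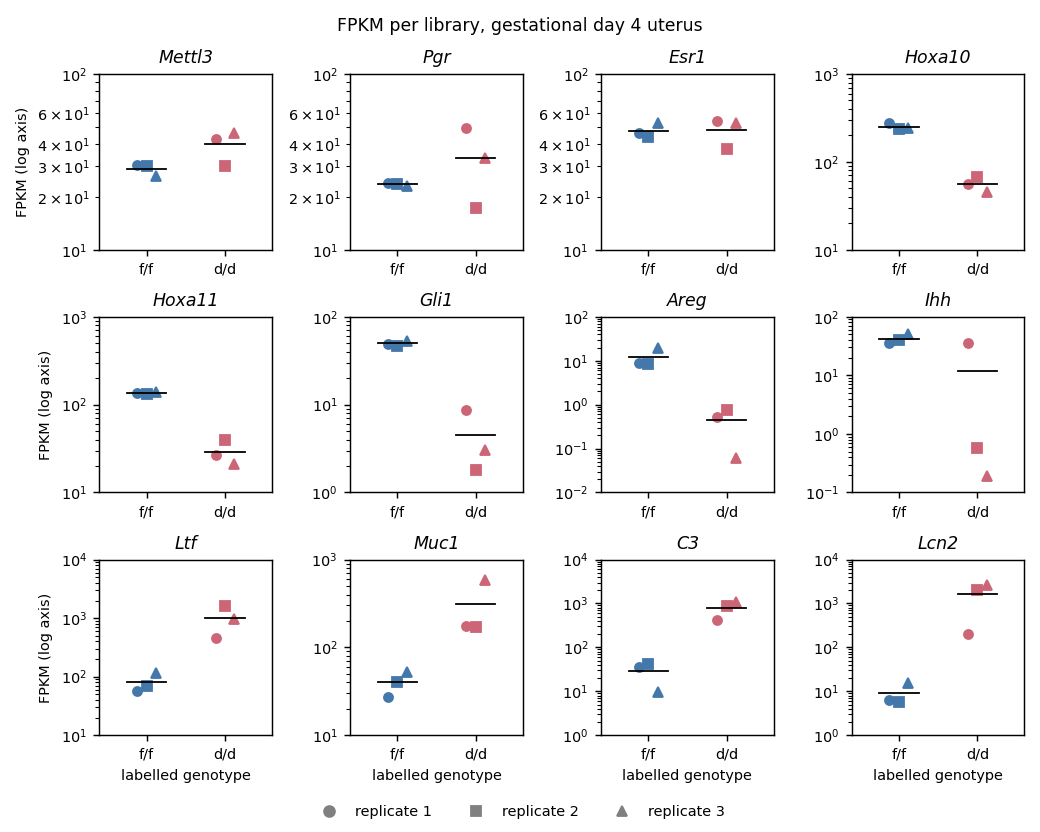
FPKM (log axis) of 12 genes in each of the 6 libraries, with f/f in blue, labelled d/d in red, the replicate number as the marker shape and the group mean as a line. Mettl3, Pgr and Esr1 overlap between genotypes, Hoxa10, Hoxa11, Gli1 and Areg are lower in all 3 labelled d/d libraries, Ihh is at 35.05 FPKM in d/d replicate 1 and at 0.580 and 0.189 in d/d replicates 2 and 3, and Ltf, Muc1, C3 and Lcn2 are higher in all 3.

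Genes that progesterone signalling raises in the uterus fell as a group (camera adjusted p = 1.16e-09 over 31 lists), a call that an estimated correlation ended (adjusted p = 0.874). Of 23 measured members, 9 were lower, 0 were higher and 14 did not pass over all genes, and 17 were lower and 1 higher adjusted over the list alone. Hoxa10 and Hoxa11, homeobox genes needed in the uterine stroma for implantation (chromosome 6, 52231197 to 52240854 and 52242106 to 52245810), fell from 253 ± 23.4 to 56.1 ± 10.7 FPKM and from 135 ± 3.51 to 29.2 ± 9.53 (n = 3 each), with log2 fold changes of -2.16 (SE 0.17, limma adjusted p = 0.00608) and -2.22 (SE 0.23, adjusted p = 0.00887). Hand2, a stromal transcription factor gene that restrains growth factor signals to the epithelium, fell by 1.71 on the log2 scale, Zbtb16 by 2.59 and Fkbp5, a co-chaperone gene of steroid receptors, by 1.23. Gli1 and Ptch1, which respond to hedgehog signals, fell by 3.41 and 1.97. The epithelial growth factor gene Areg (chromosome 5, 91139599 to 91148432) fell from 12.4 ± 6.35 to 0.448 ± 0.357 FPKM (adjusted p = 0.0118), and Il13ra2 fell by 3.55 on the log2 scale.

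Other epithelial members of the progesterone list did not pass, and several of them differed between the labelled d/d libraries. Ihh, the hedgehog ligand gene that the epithelium makes under progesterone (chromosome 1, 74945315 to 74951672), averaged 42.1 ± 8.30 FPKM in f/f libraries and was at 35.05, 0.580 and 0.189 in d/d replicates 1, 2 and 3 (limma adjusted p = 0.154). Sox17 was at 280, 35.9 and 82.0 FPKM in these libraries against an f/f mean of 243, Acod1 at 62.2, 30.1 and 1.21 against 70.1, and Lrp2 at 16.7, 0.0265 and 1.95 against 42.0 (adjusted p = 0.266, 0.302 and 0.0791). Calca instead was low in all 3 labelled d/d libraries: it was at 2.88, 3.81 and 18.1 FPKM in f/f replicates 1 to 3 and at 0.169 and 0.193 in d/d replicates 1 and 2, and was listed at 0 in d/d replicate 3 (adjusted p = 0.0504). Cbr2 and Prap1 had positive log2 fold changes of 1.54 and 1.81 that did not pass (adjusted p = 0.141 and 0.380). The mean log2 fold change of the list was -1.75. The number of lower members was 0 without f/f replicate 1, 1 without f/f replicate 2, 4 without f/f replicate 3 and 16 without d/d replicate 1.

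Genes that estrogen raises in the uterus were higher as a group (camera adjusted p = 0.000539), a call that an estimated correlation ended (adjusted p = 0.874), as did fry (0.0505). Of 19 measured members, 8 were higher, 1 was lower and 10 did not pass over all genes, and 10 were higher and 2 lower adjusted over the list alone. Ltf, the lactoferrin gene (chromosome 9, 111019271 to 111042767), rose from 80.3 ± 31.1 to 1000 ± 566 FPKM (n = 3 each), with a log2 fold change of 3.51 (SE 0.49, limma adjusted p = 0.0192). Muc1, a mucin gene of the epithelial surface, rose from 40.3 ± 12.8 to 313 ± 240 FPKM (log2 fold change 2.72, adjusted p = 0.0352), and Padi4 rose by 2.31. C3, Lcn2, Clca1 and Sprr2f, given above, are also members. Sprr2e was listed at 0 in f/f replicates 1 and 2, at 0.271 FPKM in f/f replicate 3 and at 1.36, 1.26 and 1.02 in the labelled d/d libraries. The member that was lower over all genes was Fgf1, a growth factor gene, from 27.4 ± 7.32 to 4.36 ± 1.49 FPKM (log2 fold change -2.41, adjusted p = 0.0117). Fgf1 overlaps Arhgap26 on the other strand by 90800 bp. Wnt11 had a larger log2 fold change of -3.42 that did not pass (adjusted p = 0.129). It averaged 43.7 ± 3.05 FPKM in f/f libraries and was at 30.2, 1.10 and 0.104 in d/d replicates 1, 2 and 3. Greb1, at 2.69 ± 0.729 and 14.1 ± 10.8 FPKM, did not pass (adjusted p = 0.0713), nor did Igf1, at 156 ± 33.8 and 76.3 ± 58.7 (adjusted p = 0.205).

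The mean log2 fold change of the estrogen list was 2.00. Markers of the luminal and shared epithelium, where several of these genes are expressed, had a mean log2 fold change of 0.71 over 14 members (camera adjusted p = 0.0322; adjusted p = 0.874 with an estimated correlation and 0.342 with fry). Against the f/f mean their medians (log2) were 0.99, -0.20 and 1.40 in d/d replicates 1, 2 and 3, where those of the estrogen list were 1.35, 1.25 and 3.07. Of the estrogen list, 0 members were higher without f/f replicate 1, 0 without f/f replicate 2 and 1 without f/f replicate 3.

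Cell cycle genes were slightly higher together, with no single member past the threshold. None of 27 measured members passed over all genes or adjusted over the list alone, and the mean log2 fold change was 0.34 (camera adjusted p = 0.00581; adjusted p = 0.874 with an estimated correlation and 0.342 with fry). The replication helicase genes Mcm6 and Mcm2 were at 31.8 ± 1.79 and 19.5 ± 0.429 FPKM in f/f and at 44.6 ± 2.37 and 29.5 ± 5.16 in labelled d/d libraries (limma adjusted p = 0.0537 and 0.0743, n = 3 each). Mki67 was at 13.9 ± 3.14 and 19.2 ± 6.34 FPKM (adjusted p = 0.351), and Tyms had a log2 fold change of -0.37 (adjusted p = 0.161). Without d/d replicate 3 the mean of the list was 0.15 and the call was lost (camera adjusted p = 0.127). Against the f/f mean, the medians of the list (log2) were 0.31, -0.09 and -0.13 in f/f replicates 1, 2 and 3. They were 0.20, 0.22 and 0.63 in d/d replicates 1, 2 and 3, so d/d replicates 1 and 2 lay under f/f replicate 1.

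Genes of the machinery that writes, removes and reads N6-methyladenosine were higher as a group (mean log2 fold change 0.32, camera adjusted p = 0.0138; adjusted p = 0.874 with an estimated correlation and 0.176 with fry). Of 17 measured members, 2 were higher and 0 lower over all genes, and 6 were higher and 0 lower adjusted over the list alone. Over all genes, 5 were higher without d/d replicate 2 and 0 without any 1 of the f/f libraries. Ythdf2, a reader gene, rose from 22.4 ± 3.04 to 42.2 ± 5.09 FPKM and Rbm15b, a writer complex gene, from 8.30 ± 0.438 to 14.5 ± 0.407 (n = 3 each, limma adjusted p = 0.0287 and 0.0251). Rbm15b overlaps Manf on the same strand by 6511 bp. The writer complex genes Rbm15 and Wtap had log2 fold changes of 1.03 and 0.43 (adjusted p = 0.0635 and 0.0666). The call of the list was lost without d/d replicate 1 (adjusted p = 0.0694) and without d/d replicate 3 (adjusted p = 0.0538).

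Hedgehog pathway genes were lower, and single Wnt and decidual genes moved both ways. Of 11 measured hedgehog genes, 3 were lower and 0 higher over all genes, and 5 were lower and 0 higher adjusted over the list alone (mean log2 fold change -1.26, camera adjusted p = 0.00411; adjusted p = 0.874 with an estimated correlation and 0.0505 with fry). Gli1 and Ptch1, given above, were among them. Without f/f replicates 1, 2 and 3, 0, 1 and 1 hedgehog genes were lower over all genes. Of 16 measured Wnt pathway genes, 3 were higher and 2 lower over all genes, and 4 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.743). Wnt7b rose from 0.567 ± 0.635 to 15.6 ± 2.03 FPKM, Wnt4 from 1.39 ± 0.618 to 17.5 ± 8.57 and the Wnt antagonist gene Sfrp1 from 2.24 ± 0.802 to 9.80 ± 4.03, while Wnt6 fell by 1.96 on the log2 scale and Lef1, named after its value was seen, was the other member that fell.

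Of 8 measured decidual genes, 2 were higher and 2 lower over all genes, and 3 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.952, with a mean log2 fold change of 0.44 but a downward camera direction). Wnt4 and the transcription factor gene Cebpb rose, the latter from 22.3 ± 7.41 to 97.4 ± 44.3 FPKM, and Hoxa10 and Hand2 fell. Of 16 receptivity and prostaglandin genes, 2 were higher and 0 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.743, mean log2 fold change 0.19, median -0.03). Over all genes, 1 was higher and 3 were lower without d/d replicate 1, and 4 were higher and 0 lower without d/d replicate 2. With all libraries the higher members were Wnt7b and Lifr, the receptor gene of leukemia inhibitory factor, which rose from 5.13 ± 1.10 to 15.7 ± 5.06 FPKM (limma adjusted p = 0.0371). Hbegf and Msx2 had log2 fold changes of 0.76 and 2.11 that did not pass (adjusted p = 0.0842 and 0.0961).

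Among stress and growth lists, several single genes rose. Of 16 genes of the unfolded protein and integrated stress response, 3 were higher and 0 lower over all genes, and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.187). Over all genes, 0 were higher without any 1 of the f/f libraries. The chaperone gene Hspa5 rose from 201 ± 8.40 to 443 ± 125 FPKM, Pdia4 by 0.96 and Chac1 by 1.29 on the log2 scale. Of 15 p53 targets and apoptosis genes, 3 were higher and 1 lower over all genes, and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.223). Without f/f replicates 1, 2 and 3, 0, 0 and 1 of them were higher over all genes. Gdf15 rose by 2.87, the cell cycle inhibitor gene Cdkn1a by 1.62 and Pmaip1 by 0.99, while Ccng1 fell by 0.53. Myc was the 1 immediate early gene of 15 that changed, with 0 higher and 1 lower over all genes and adjusted over the list alone, and it fell from 73.9 ± 9.02 to 29.2 ± 3.55 FPKM (limma adjusted p = 0.0116; camera adjusted p = 0.826 for the list).

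Cholesterol biosynthesis genes were higher as a list without a single member past the threshold. None of 18 passed over all genes or adjusted over the list alone, and the mean log2 fold change was 0.95 (camera adjusted p = 0.00369; adjusted p = 0.874 with an estimated correlation and 0.342 with fry). Cyp51 was at 12.6, 25.9 and 47.4 FPKM in d/d replicates 1, 2 and 3 against an f/f mean of 6.93. Without d/d replicate 3 the mean of this list was 0.40. Of 24 interferon-stimulated genes 1, Oas3, was higher and 0 lower over all genes and 0 adjusted over the list alone (camera adjusted p = 0.952, mean log2 fold change 0.04, median -0.05, camera direction downward), and 1 was higher and 4 were lower over all genes without d/d replicate 1. No member passed, over all genes or over the list alone, among 20 fibrillar collagen and matrix genes (camera adjusted p = 0.962, mean 0.15 with a downward camera direction), 58 respiratory chain genes (0.514) or 75 cytoplasmic ribosomal protein genes (0.2999). The respiratory chain and ribosomal lists were called lower without d/d replicate 3 (camera adjusted p = 6.51e-05 and 0.000982) and with weights per library (0.0115 and 0.0153).

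Markers of several cell types differed between the genotypes. Of 14 markers of the luminal and shared epithelium, 3 were higher and 0 lower, over all genes and adjusted over the list alone. Over all genes, 8 were higher and 0 lower without d/d replicate 2, 2 were higher and 1 lower without d/d replicate 1, and 0 changed without any 1 of the f/f libraries. Krt7 rose by 2.61 and Epcam by 1.54 on the log2 scale, while Calb1 was at 202, 4.54 and 0.882 FPKM in d/d replicates 1, 2 and 3 against an f/f mean of 286 (limma adjusted p = 0.145). Of 9 glandular markers, 1 was higher and 3 lower over all genes, and 2 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.514). Aldh1a1 rose by 2.17 on the log2 scale, and Spink1, Wfdc3 and Ttr were lower, the last at 1.89, 4.70 and 6.94 FPKM in f/f libraries and 0.118 in d/d replicate 1, and listed at 0 in d/d replicates 2 and 3. None of 11 stroma markers passed, over all genes or over the list alone (mean -0.17, camera adjusted p = 0.700; 2 higher without d/d replicate 1 and 2 lower without d/d replicate 2), with Vim at a log2 fold change of -1.27 and Lum at 0.98.

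Endothelial and smooth muscle markers were lower and macrophage markers higher as lists. Of 11 endothelial markers, 0 were higher and 1 lower over all genes, namely Cdh5 (log2 fold change -1.32), and 0 were higher and 6 lower adjusted over the list alone (mean -0.54, camera adjusted p = 0.0110; adjusted p = 0.874 with an estimated correlation). Of 11 smooth muscle markers, 0 were higher and 2 lower, over all genes and adjusted over the list alone, namely Synm and Smtn at -1.19 and -0.95 (mean -0.74, camera adjusted p = 0.0474; adjusted p = 0.874 with an estimated correlation). Of 12 macrophage and dendritic cell markers, 1 was higher and 0 lower, over all genes and adjusted over the list alone, namely Cd68 at 2.45 (mean 1.49, camera adjusted p = 0.0110; adjusted p = 0.874 with an estimated correlation). Fry called none of these lists (adjusted p = 0.342 for each), and the smooth muscle call was also lost with upper quartile scaling (0.0849), median-of-ratios scaling (0.0515) and 1 weight per genotype (0.0667, chosen after the data had been seen). With a library left out the mean ran from 0.45 to 1.22 for the epithelial list, from -0.78 to -0.33 for the endothelial (-0.53 without d/d replicate 1), from -1.16 to -0.34 for the smooth muscle and from 0.56 to 2.33 for the macrophage list. Leaving out d/d replicate 1 ended the epithelial, endothelial and smooth muscle calls (adjusted p = 0.255, 0.0525 and 0.309), d/d replicate 2 the smooth muscle and macrophage calls (0.116 and 0.109), d/d replicate 3 the epithelial and endothelial calls (0.0751 and 0.0582), and f/f replicates 1 and 2 the smooth muscle call (0.0506 and 0.186).

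The other marker lists were not called with all libraries in the main test. Calls appeared for higher neutrophil markers with weights per library (camera adjusted p = 0.0423) and without d/d replicate 3 (0.0168), for lower oviduct and ciliated cell markers with the replicate block (0.0413) and without d/d replicate 3 (0.0290), and for lower red blood cell markers without f/f replicate 3 (0.0416). Of 6 neutrophil markers none passed, over all genes or over the list alone (camera adjusted p = 0.168). Of 10 lymphocyte and natural killer cell markers, Cd79b was higher and Prf1 lower over all genes, and 1 was higher and 4 lower adjusted over the list alone (0.398). Of 3 mesothelial markers, Wt1 was lower and 0 were higher over all genes, and 1 was higher and 1 lower adjusted over the list alone (0.994, mean 0.17 with a downward camera direction). Wt1 was at 56.8 to 75.3 FPKM in f/f libraries and Upk3b at 0.153 to 0.650, so Wt1 may not mark mesothelium here. None passed over all genes among 4 red blood cell (0.142), 4 fat (0.870), 4 oviduct and ciliated cell (0.0967), 2 ovary (0.751) and 3 blastocyst markers (0.514). Adjusted over the list alone, 2 oviduct and ciliated cell markers and 1 blastocyst marker were lower, and 0 of the other 3 lists. The 3 measured blastocyst markers were Krt8, which is also on the epithelial list, Eomes and Gata6. Pou5f1 and Cdx2, named after their values were seen, were listed at 0 in all libraries, so the measured markers may not mark blastocysts here.

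**Figure D2:**
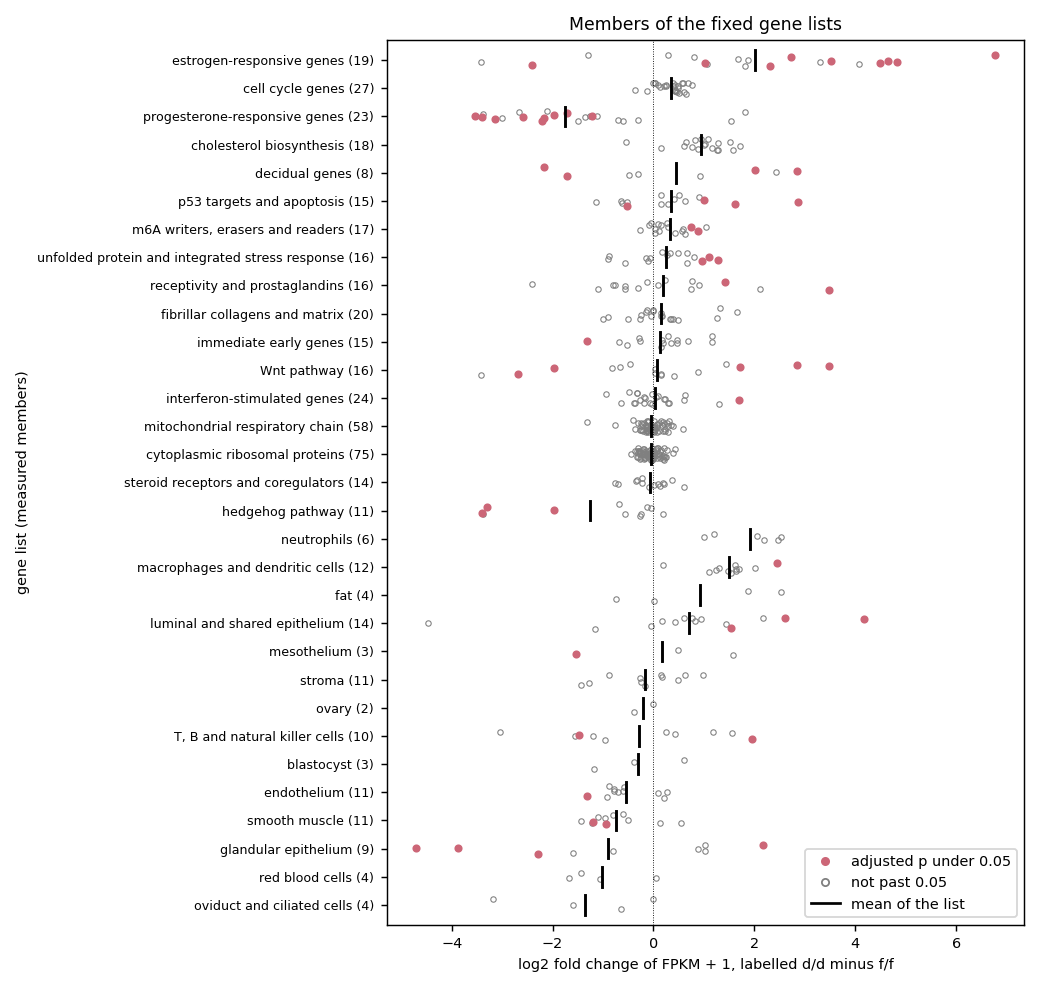
Log2 fold change of FPKM + 1, labelled d/d minus f/f, of each measured member of the 31 lists (points; filled where the limma adjusted p was under 0.05), with the mean of each list as a bar and the number of measured members in brackets. The means of the progesterone, estrogen and cell cycle lists lie at -1.75, 2.00 and 0.34.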

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

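The tests with weights per genotype were chosen after the data had been seen. The count of 947 changed genes ranged from 657 to 1110 over the alternatives that kept all libraries and had no block, and the progesterone and estrogen lists kept their direction in every alternative run, with means of -2.27 to -1.50 and 1.64 to 2.38. The count of at least 2-fold changes was 414 with a filter at a mean of at least 5 FPKM, where fewer genes are tested. With each library left out in turn, the count of changed genes ran from 0 to 1367 and of at least 2-fold changes from 0 to 895. It was 0, 30 and 111 without f/f replicates 1, 2 and 3, and 1319, 1367 and 1005 without d/d replicates 1, 2 and 3. The log2 fold change of Mettl3 ran from 0.31 to 0.62 (adjusted p = 0.0422 to 0.432). The mean of the cell cycle list ran from 0.15 to 0.46 with a library left out and was 0.21 with weights per library (adjusted p = 0.0995). The cause of these shifts was not tested. With an estimated correlation the means of -1.75, 2.00 and 0.34 of the progesterone, estrogen and cell cycle lists were no longer called (camera adjusted p = 0.874). The adjustment gave this same value to many lists. Before adjustment, p in that form of camera was 0.0396, 0.0634 and 0.451 for these 3 lists. With fry the 2.00 and 0.34 of the estrogen and cell cycle lists were not called (adjusted p = 0.0505 and 0.342), while the progesterone list was (0.0440). Of 62 called genes named in the text, 19 kept their call in all alternatives without a left-out library, 0 kept it in all alternatives and 0 turned direction.

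Most results that turned direction lay near 0. The log2 fold change of Esr1 was -0.00015 with a pseudocount of 0.1, -1.68e-05 with a pseudocount of 0.5, -0.0931 with quantile normalization, -0.0807 with upper quartile scaling and -0.00926 with median-of-ratios scaling, and ran from -0.0905 to 0.164 with a library left out. S100a9 was at 2.63, 0.401 and 4.22 FPKM in f/f and at 7.09 and 560 in d/d replicates 1 and 2, and was listed at 0 in d/d replicate 3. Its log2 fold change of 2.47 is not near 0 and rests on d/d replicate 2: with a library left out it ran from -0.0689 to 4.50. Interferon-stimulated genes had a mean of -0.0161 with quantile normalization and -0.0409 with upper quartile scaling. Weights per library gave means of 3.87e-05 for the steroid receptors and coregulators and -0.0409 for the fibrillar collagens and matrix, the ovary list was at 0.0950 with no filter and the blastocyst list at 0.11 with the filter at a mean of at least 5 FPKM. With a library left out, list means ran from -0.199 to 0.0345 (steroid receptors and coregulators), -0.22 to 0.38 (Wnt pathway), -0.34 to 0.32 (interferon-stimulated genes, adjusted p = 0.0141 without d/d replicate 1), -0.0656 to 0.240 (immediate early genes), -0.24 to 0.50 (fibrillar collagens and matrix), -0.24 to 0.10 (mitochondrial respiratory chain, adjusted p = 6.51e-05 without d/d replicate 3), -0.178 to 0.0445 (cytoplasmic ribosomal proteins, adjusted p = 0.000982 without it), -0.49 to 0.15 (stroma), -0.91 to 0.26 (T, B and natural killer cells), -0.19 to 0.67 (mesothelium) and -0.363 to 0.0722 (ovary). The cause was not tested.

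No pairing of the libraries by replicate number was seen, and the labels state none. Deviations from the group means correlated at -0.02, 0.02 and -0.02 for numbers 1, 2 and 3, and 0 of the 6 libraries correlated best with its own number. This cannot exclude a weak shared factor, because the deviations come from 3 libraries per genotype. A fit with the replicate block called 100 genes, 51 higher and 49 lower, and the same number, 100, at least 2-fold. The alternatives planned for counts (DESeq2 with its size factors, no filter on low counts, and DESeq2 size factors in another test) were not run, because the values were taken as FPKM. Without read numbers, counting error cannot be separated from the spread between libraries, which limits genes with low values most.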

Other observations

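The labelled d/d libraries differed from one another in gene groups that the averages hide, and Lpar3, Msx1 and Ptprc are named here after their values were seen. In d/d replicate 1, Ihh stood at 83.3% of the f/f mean, Sox17 at 115%, Acod1 at 88.6%, Cyp26a1 at 85.2%, Calb1 at 70.7%, Wnt11 at 69.1%, Lpar3 at 63.2% and Msx1 at 160%, while Lrp2 stood at 39.7%, Areg at 4.17%, Il13ra2 at 8.06%, Calca at 0.169 FPKM, Gli1 at 17.5% and Hoxa10 at 22.3%. In d/d replicates 2 and 3, Ihh stood at 1.38% and 0.449% of the f/f mean. Markers of macrophages and dendritic cells had a median of 3.37 above the f/f mean (log2) in d/d replicate 2, 1.31 in d/d replicate 1 and -0.07 in d/d replicate 3. Cholesterol biosynthesis genes had medians of 0.11, 0.77 and 2.26 in d/d replicates 1, 2 and 3, and Padi1 was at 21.8, 12.2 and 533 FPKM. Fat markers had a median of 2.37 in d/d replicate 1, with Cfd at 141 FPKM there and at 9.70 and 0.0875 in d/d replicates 2 and 3.

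The list of lymphocyte and natural killer cell markers was not called (camera adjusted p = 0.398), and its members differed between the labelled d/d libraries, with medians against the f/f mean (log2) of -0.56, 1.11 and -1.47 in d/d replicates 1, 2 and 3. Of its members, Prf1, the perforin gene, fell from 3.51 ± 0.863 to 0.631 ± 0.392 FPKM (limma adjusted p = 0.0289, n = 3 each). Gzmb and Ncr1 did not pass: Gzmb was at 36.9, 20.5 and 26.4 FPKM in f/f and 3.33, 7.10 and 0.150 in d/d replicates 1, 2 and 3 (adjusted p = 0.0532), and Ncr1 at 4.16 ± 2.38 and 0.691 ± 0.479 FPKM (adjusted p = 0.0631). Ovgp1, an oviduct marker, was at 88.2, 17.7 and 29.4 FPKM in f/f and 15.6, 1.36 and 0.741 in labelled d/d libraries (adjusted p = 0.101).

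Progesterone-responsive genes of the stroma (Hoxa10, Hoxa11, Hand2, Ptch1, Gli1, Zbtb16 and Fkbp5) were lower, and Nr2f2 did not pass (log2 fold change -0.70, limma adjusted p = 0.0516). The median log2 fold change of these 8 genes was -2.07. They are a part of the 23 measured members of the progesterone list, whose median, epithelial members included, was -1.97. Bmp2, another member, was left out of the group and did not pass (log2 fold change -0.31, limma adjusted p = 0.516). The 8 genes were not drawn by a stated rule, so their median may overstate the fall of progesterone-responsive genes in the stroma. A lower share of stromal cells would lower stroma markers alike, and their median log2 fold change was -0.16 (SE 0.23 over 11 markers), with a list mean that ran from -0.49 to 0.15 with a library left out. Each SE beside a marker median, here and in the next paragraph, is the SD over the markers divided by the square root of their number. It treats the markers as independent and measures no spread between uteri. Tests in each library, chosen after that, gave medians against the f/f mean of -0.82 (SE 0.17), 0.49 (SE 0.21) and 0.0830 (SE 0.39) for the markers in d/d replicates 1, 2 and 3, and of -1.58, -1.82 and -2.38 for the 8 genes. The markers were thus lower in d/d replicate 1, where fewer stromal cells stay open as part of the fall. In no library was the median of the markers low enough for the whole fall of the 8 genes, whose choice may deepen that fall. The markers moved both ways, however. Pdgfra was at 41.1, 32.5 and 50.7 FPKM in f/f and at 9.97, 31.7 and 9.06 in labelled d/d libraries. Vim was at 562, 575 and 649 and at 211, 403 and 174, while Lum was at 141, 137 and 123 and at 121, 478 and 321. The median therefore cannot exclude a loss of some stromal cells. Another scaling of the FPKM values left the median of the 8 genes between -2.14 and -2.08, which argues against scaling. A lower response of the stroma to progesterone in the labelled d/d uteri may be a biological explanation and remains a hypothesis, because hormone levels and the day of sampling were not tested, the same libraries gave the pattern and the tests, and the Mettl3 values did not check the labels.

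Some genes, picked after their values were seen because they stood near the f/f level in d/d replicate 1 alone, had a median of 84.2% of the f/f mean there (Ihh, Sox17, Acod1, Cyp26a1, Calb1, Wnt11, Lpar3 and Msx1). Of these, Ihh, Sox17, Acod1 and Cyp26a1 stand in the progesterone list, Wnt11 in the estrogen list and Calb1, Lpar3 and Msx1 in other lists. Lrp2, Il13ra2, Areg and Calca, also of the progesterone list, did not stand near the f/f level there. The pattern and the tests below thus concern the 8 picked genes alone. The tests of mixed f/f RNA were chosen after the pattern had been seen, as were the comparisons of epithelial markers with each single library, and the other tests here were chosen before their values were seen. The first test of f/f RNA mixed into that library, on 182 genes at least 4-fold lower in both other d/d libraries, did not decide: the share of the f/f level regained had an interquartile range of 0.447, and 30.2% of the genes regained under 0.1, but 7.69% regained over 0.75 where the criterion asked for at least 10%. A second criterion was written after that outcome. A mixture cannot hold more f/f RNA than its least abundant f/f genes allow, and the percentile 10 of these 182 genes was 5.36% of the f/f mean, far under the 84.2% that the pattern would need. More epithelial cells would raise shared epithelial markers by about as much as these genes (2.23 on the log2 scale), but their median was -0.61 (SE 0.23) against the higher of d/d replicates 2 and 3. Against d/d replicate 2 alone they were higher by a median of 1.18 (SE 0.15), which goes part of the way to the 3.14 of the 8 genes, and against d/d replicate 3 alone the 8 genes were higher by 3.68 while the markers were lower. This argues against more epithelial cells as the whole cause. Incomplete deletion in that uterus and a different hour of sampling stay open and were not tested.

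Neutrophil genes were high in d/d replicate 2, where 9 of the 10 on the list had their highest value. S100a8 was at 406 FPKM in d/d replicate 2, at 4.91 and 0.238 in d/d replicates 1 and 3 and at 0.664 to 2.42 in f/f libraries, and Ptprc, a gene of all leukocytes, was at 65.5 FPKM in d/d replicate 2. Blood carried into the sample would bring red cell transcripts, but red blood cell genes summed to 30.6 FPKM in d/d replicate 2 against 215 in the highest other library, which argues against blood. No biological explanation was tested, since the labels set that library apart in nothing.

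The 6 libraries can be split into 3 and 3 in 10 ways. The real split was the 1 that gave as many as 947 changed genes and as many as 623 changed at least 2-fold, and the highest count of the other splits was 0 in both cases (limma; counts at an unadjusted p were not taken for these splits). With 10 splits the share cannot fall under 0.05.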
